A study of Mus musculus with 10 samples.

How the data were processed

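Whole liver RNA from 5 control and 5 LKO male mice was measured by bulk RNA sequencing. Per the labels' protocols, RNA came from frozen liver, ribosomal RNA was removed with FastSelect, libraries were made with a stranded Kapa Hyper kit, and all were pooled on 1 NovaSeq lane and read from 1 end for 101 cycles. The deposited table holds a whole-number count per gene and library, not normalized, with genes given as NCBI Gene numbers. The submitters' processing notes name bcl2fastq 2.20, DESeq2 and the genome build GRCm39. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here. Reads shared by near-identical or overlapping genes may therefore have been split or dropped in ways that move single genes.

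All 10 columns of the table were matched to samples by name, and 0 columns were not used. Symbols came from a RefSeq gene table of assembly GRCm38.p6, used for names and neighbours alone, so no coordinates are printed. It matched 25275 of 27179 genes, and genes without a match held 0.693% of counts and stayed in the tests. Among the tested genes, 18 shared all 10 counts with another gene. No pair of libraries in a group agreed within sampling noise. The lowest chi-square per degree of freedom was 51.6 in control and 34.5 in LKO. Correlations of log2 CPM ran from 0.959 to 0.988 within control and from 0.944 to 0.989 within LKO.

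Differences were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, libraries were scaled with TMM, and genotype was the only term of the quasi-likelihood F test, two-sided. P-values were adjusted by Benjamini-Hochberg over 15226 genes, with a threshold of 0.05. The common biological coefficient of variation was 0.242. CPM values are TMM-scaled, standard errors were derived from the fold change and its F statistic, and a count of 3, the floor for a gene with 0 counts, equals 0.0698 CPM in control 5 and 0.113 CPM in control 1. Such floors cover counting error only. The median log2 fold change of all genes was -0.00 and moved by less than 0.1 under the other planned scalings. It was 0.235 with total counts.

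Tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The rule took Lpcat3 and, per direction, the 10 genes with the largest change among those with an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between groups, leaving out unnamed models. Places left over were filled by smallest p, and each list gave up to 4 members with the smallest p. Lists with at least 3 tested members were tested with limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01), two-sided, adjusted over 37 lists. Members were also adjusted over the list alone. Estimated correlation, fry and an exact permutation of list means over all 252 assignments (smallest possible p 0.00794) were set beside it. Some genes are in more than 1 list, such as Lpl, Abcc4 and Cyp7b1.

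Alternatives were other scalings, filters and thresholds, DESeq2 1.42.0, limma voom with quality weights, robust dispersion, the replicate number as a block, the title code as a covariate, and leaving out each library or the A54 samples. Added after seeing the data were scaling to total counts, leaving out control 4 with LKO 3, 1 surrogate variable (sva 3.50.0), the permutation of list means, and an adjusted p under 0.1. The first edgeR fit was run by mistake without the legacy option (8 genes called). The results given use that option, and the first fit is kept as an added alternative. Figures were drawn with matplotlib 3.10.9.

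The tests were checked on simulated counts with the real means, library sizes and dispersions, genes drawn independently. For LKO against control, edgeR recovered 69 of 98 genes changed 2-fold and 89 of 98 changed 4-fold among 15063 genes, with 8 false calls. DESeq2 recovered 70 of 97 and 94 of 97 among 15067 genes, with 49 false calls. Camera found 5 of 5 shifted lists and called 1 of 32 unshifted lists, while the estimated correlation and fry found 5 of 5 and called 0. Those lists had independent members, unlike real ones.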

Results

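Liver RNA was sequenced from male C57BL/6 mice carrying floxed Lpcat3 alleles, either without Cre (control) or with Cre recombinase driven by the albumin promoter (LKO), which deletes the gene in hepatocytes. Lpcat3 encodes an acyltransferase of membrane phospholipid remodelling that places polyunsaturated fatty acids into lysophospholipids. Mice of both groups had been fed for 12 weeks a diet that produces nonalcoholic steatohepatitis. Each group held 5 mice, with 1 library per mouse. The libraries held 26914124 counts (control 4) to 46727182 counts (control 5). After removal of genes with low counts, 15226 of 27179 genes were tested. The comparison asks how loss of hepatocyte Lpcat3 alters the liver transcriptome in steatohepatitis. P-values measure the spread between these samples.

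Lpcat3 (NCBI Gene 14792) was lower in every LKO library than in any control library. Its level fell from 109 ± 13.3 CPM in control to 31.3 ± 4.65 CPM in LKO (SD, n = 5), which is 3.46-fold lower. The log2 fold change was -1.79 (SE 0.12; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000151). Control 4 had 95.7 CPM and control 5 had 94.1 CPM, while the highest LKO library, LKO 3, had 38.5 CPM. Sample titles carry the codes A54, A55 and A67, of unstated meaning, and only A54 occurs in both groups. Within A54, Lpcat3 stood at 123.9 CPM in 1 control and at 31.1 and 31.3 CPM in 2 LKO libraries. With the code as a covariate the log2 fold change was -1.99 and the edgeR adjusted p was 0.0565. Lpcat3 overlaps Emg1 in the annotation, and how the counting treated overlaps is not given in the sources used here.

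**Figure D1:**
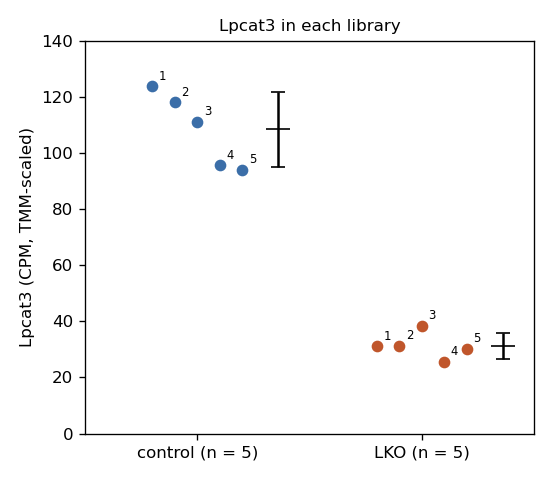
Lpcat3 in CPM in each library, numbered by replicate, with the mean and SD of each group of 5 beside the points. The 5 LKO libraries lie between 25.5 and 38.5 CPM and the 5 control libraries between 94.1 and 123.9 CPM.

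Besides Lpcat3, 9 genes changed at an adjusted p under 0.05, 4 of them higher and 5 lower in LKO (edgeR quasi-likelihood test, Benjamini-Hochberg). Dkk4 (NCBI Gene 234130), which encodes a secreted Wnt antagonist, fell by 3.21 on the log2 scale (SE 0.30; edgeR adjusted p = 0.00205), from 1.69 ± 0.607 to 0.18 ± 0.0365 CPM. Its mean abundance lies under the minimum set for named genes, so it was chosen after its values were seen. In LKO it lay between 0.146 and 0.220 CPM, near the floor of 0.0764 (LKO 4) to 0.0942 CPM (LKO 1). The size of its fall is therefore less certain than its SD in LKO conveys. Nipal1, of a family of magnesium transporters, rose from 0.809 ± 0.214 to 8.31 ± 6.03 CPM (log2 3.36, SE 0.51; edgeR adjusted p = 0.0496). Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, rose from 1.92 ± 0.472 to 9.31 ± 3.97 CPM (log2 2.28, SE 0.30; edgeR adjusted p = 0.0325). Hhipl2 rose from 0.603 ± 0.16 to 1.86 ± 0.153 CPM and the histone gene H2bc12 from 4.3 ± 0.75 to 8.59 ± 1.19 CPM (edgeR adjusted p = 0.0325 and 0.047). The desmosomal cadherin genes Dsg1c and Dsg1a fell from 14.02 ± 2.93 to 4.97 ± 1.26 CPM and from 5.02 ± 1.29 to 1.83 ± 0.351 CPM (edgeR adjusted p = 0.0325 and 0.047). They are near-identical copies, so the split of reads between them is uncertain. H2bc12 belongs to a multigene family and is uncertain for the same reason. Fam228b fell by 1.10 on the log2 scale (edgeR adjusted p = 0.047), and it overlaps Pfn4. Pla1a, which encodes a phosphatidylserine-specific phospholipase, fell by 0.74 on the log2 scale (edgeR adjusted p = 0.0496), from 15.1 ± 2.22 to 8.98 ± 0.737 CPM.

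Of the 15226 genes, 3402 had an unadjusted edgeR p under 0.05, 1956 higher and 1446 lower in LKO, where chance gives 761. In 5 of 100 splits of the samples, the real one included, as many had. The ranges of both groups were apart for 602 genes, or 3.95%, where chance gives 0.794%. Places left over under the rule for named genes went to genes that did not pass. Lama4 and Mcam, genes of vessel walls, had log2 fold changes of 0.61 and 0.62. Idh2, the mitochondrial isocitrate dehydrogenase, stood at 0.63, Acsl3 at 0.75, Htatip2 at 0.76 and Cdc42ep5 at 1.95. Plekhb1 stood at -0.71, Sdr9c7 at -1.41, Gpc4 at -0.65, Cadm4 at -1.24, the sphingosine-1-phosphate receptor gene S1pr1 at -0.66 and Chic1 at -1.70. Their edgeR adjusted p-values ran from 0.0514 (Lama4) to 0.0635 (Chic1).

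The number of genes called rested on single libraries. Without control 4 it was 2296 (1568 higher, 728 lower), and without LKO 1 it was 86. Without control 1, control 3, LKO 4 or LKO 5 it was 2, without control 5 it was 4, and without control 2 or LKO 2 it was 5. Lpcat3 and Dkk4 kept their call without any 1 of the 10 libraries. The other 8 genes all lost theirs without control 1, control 3, control 5, LKO 4 or LKO 5 and kept it without control 4 or LKO 1. Nipal1, Ppp1r3g, H2bc12, Fam228b and Pla1a also lost it without control 2, Hhipl2, H2bc12, Dsg1c, Dsg1a and Pla1a without LKO 2, and Nipal1, H2bc12, Dsg1a, Fam228b and Pla1a without LKO 3. On the first principal component, which held 56.8% of the variance, control 4 lay at 30.2, apart from the other controls (-52.7 to -30.1) and among the LKO libraries (-8.03 to 82.3). DESeq2 called 1175 genes on all 10 libraries, but on simulated counts it made 49 false calls where edgeR made 8. With the title code as a covariate, edgeR called 0 genes at an adjusted p under 0.05, and 760 had an unadjusted p under 0.05.

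**Figure D2:**
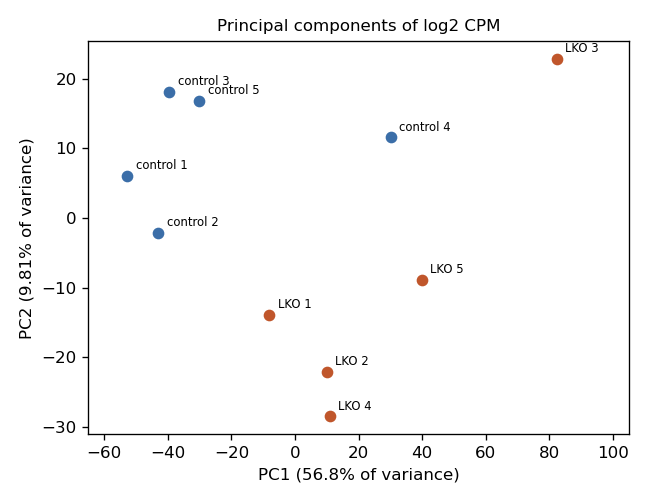
Each library on the first and second principal components of log2 CPM, coloured by group. Control 4 lies at 30.2 on the first component, where the other 4 controls lie at -30.1 or lower.

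**Figure D3:**
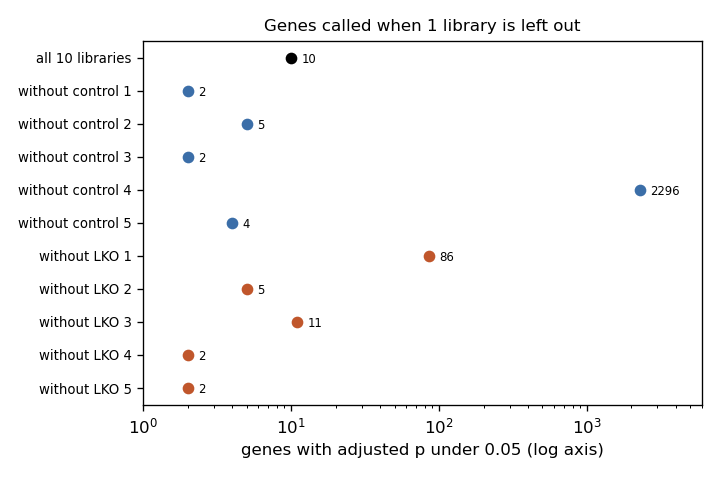
Genes with an edgeR adjusted p under 0.05 with all 10 libraries and with each library left out in turn, on a log axis. The number runs from 2 to 2296, the latter without control 4.

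Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation between genes of 0.01. Of 37 lists, 28 passed at a Benjamini-Hochberg adjusted p under 0.05, 20 higher and 8 lower in LKO. With an estimated correlation 0 lists passed, and the lowest adjusted p was 0.401. By the directional test of fry 0 passed (lowest adjusted p = 0.0654, with 16 at an unadjusted p under 0.05). An exact two-sided permutation test of list means also passed 0 (lowest adjusted p = 0.0864; 18 unadjusted). With all 10 libraries, the directional calls given for lists therefore hold under the preset correlation alone. The mixed test of fry, in which members may move either way, passed 17 lists at an adjusted p under 0.05. It gives no direction. Without control 4, 14 lists passed by fry and 0 with an estimated correlation. Where control 4 lay with the LKO libraries, leaving it out by itself widens the difference and narrows the spread of the controls. Medians and counts given without it, here and below, are therefore no separate evidence of an effect of genotype. A list mean is the mean log2 CPM of its members relative to the mean of the 5 controls, and A54 differences compare 2 LKO libraries with 1 control. Besides Lpcat3, which no list holds, no list member passed over all genes tested.

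Markers of recruited and lipid-associated macrophages rose as a list in LKO, with a median log2 fold change of 1.19 and all 20 tested members higher (camera adjusted p = 1.47e-08; adjusted p = 0.401 with an estimated correlation). Of these, 7 passed adjusted over the list alone and 0 over all genes. Lyz2, the macrophage lysozyme gene, had 47.5 ± 25.6 CPM in control and 118 ± 39.3 CPM in LKO. Cd68, a lysosomal macrophage marker, had 19.7 ± 7.73 and 33.3 ± 6.91 CPM. The list mean was 1.53 ± 0.57 in LKO, but control 4 stood at 1.86 and the other controls averaged -0.46. Within A54 the difference was 1.96. Without control 4 the median was 1.88, and 19 members passed over all genes. Kupffer cell markers, of resident macrophages, rose with a median of 0.39 (camera adjusted p = 0.021, adjusted p = 0.431 with an estimated correlation). Of the 13 tested, 9 were higher and 4 lower. The complement genes C1qa, C1qb and C1qc and the F4/80 gene Adgre1 were the 4 of 13 that passed adjusted over the list alone, with log2 fold changes of 0.66, 0.88, 0.65 and 0.62. LKO 4 stood at 0.75 in the Kupffer list mean and the other LKO libraries between 0.01 and 0.21. The list did not pass without LKO 4 (camera adjusted p = 0.134) or without control 4 (camera adjusted p = 0.108). In control 4 the value was -0.27 in this list, and the A54 difference was -0.03.

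Cytokines and chemokines rose with a median of 0.80, 19 of 20 higher (camera adjusted p = 8.65e-07; adjusted p = 0.401 with an estimated correlation). Ccl4, Ccl3 and Tnf passed adjusted over the list alone, with log2 fold changes of 2.09, 1.84 and 1.43. All 3 are low in abundance, with LKO means of 0.733, 1.33 and 1.02 CPM. The value in control 4 was 0.81 in this list, and the A54 difference was 0.63. Neutrophil markers rose with a mean log2 fold change of 1.41 over 5 tested members (camera adjusted p = 0.000921; adjusted p = 0.401 with an estimated correlation). S100a8 had 0.397 ± 0.181 CPM in control and 1.71 ± 0.997 CPM in LKO. Of the 5, 4 passed adjusted over the list alone, control 4 stood at 0.86 and the A54 difference was 1.23. Interferon-stimulated genes rose, with a median of 0.69 and 28 of 28 higher (camera adjusted p = 0.000285; adjusted p = 0.546 with an estimated correlation). Here the LKO mean was 0.50 ± 0.65, with LKO 3 at 1.60 and the other LKO libraries between 0.00 and 0.56. Without LKO 3 the median was 0.20 (camera adjusted p = 0.0125). Control 4 stood at 0.31, and the A54 difference was 0.17. Lymphocyte markers also rose as lists. T and NK cell markers had a median of 0.64 (camera adjusted p = 0.0111; adjusted p = 0.479 with an estimated correlation), with Cd8a at 1.17 and Cd4 at -0.81. B and plasma cell markers had a median of 0.54 (camera adjusted p = 0.021; adjusted p = 0.459 with an estimated correlation), with Cd22 at 0.77. In neither list did a member pass adjusted over the list alone. The list mean of control 4 was 0.87 and 0.35, and the A54 differences were 0.61 and 0.15. Without control 4 the T and NK median was 1.20, and without LKO 3 that list did not pass (camera adjusted p = 0.0526). The B and plasma list did not pass without LKO 3, LKO 5 or control 5 (camera adjusted p = 0.0572, 0.0528 and 0.0645). With a filter of at least 1 CPM in 5 libraries, the T and NK list median was -0.27.

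Genes of fibrosis and extracellular matrix rose with a median of 1.04, 34 of 37 higher (camera adjusted p = 1.78e-08; adjusted p = 0.431 with an estimated correlation). Adjusted over the list alone, 5 members passed as higher and 1 as lower. Col4a1, a basement membrane collagen, had 72.0 ± 26.3 CPM in control and 148 ± 57.2 CPM in LKO, and the cross-linking enzyme gene Loxl2 had 10.7 ± 3.51 and 19.4 ± 4.99 CPM. Fibronectin (Fn1), made in quantity by hepatocytes, went the other way, from 2421 ± 163 to 1488 ± 212 CPM. For control 4 it was 1.12 in the list, inside the LKO range, with the other controls at -0.28 and an A54 difference of 1.13. Without LKO 3 the median was 0.55 (camera adjusted p = 4.1e-07). Without control 4, 27 members passed as higher over all genes. Stellate cell markers rose with a median of 0.48 (camera adjusted p = 0.00123; adjusted p = 0.401 with an estimated correlation), with Des at 0.59, and 0 passed adjusted over the list alone. Its mean in control 4 was 0.44 in this list and the A54 difference was 0.44.

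Sinusoidal endothelial markers rose, with a median of 0.24 and 18 of 19 higher (camera adjusted p = 0.000921; adjusted p = 0.401 with an estimated correlation). Pecam1, Cdh5 and Stab1 passed adjusted over the list alone, with log2 fold changes of 0.37, 0.34 and 0.38. The mean of control 4 was -0.05 and the A54 difference was 0.18. Cholangiocyte and ductular markers rose with a median of 1.57 (camera adjusted p = 0.0156; adjusted p = 0.568 with an estimated correlation), and 0 of 11 passed adjusted over the list alone. Sox4 stood at 1.57 and Epcam at 2.16 (1.25 without LKO 3), LKO 3 at 2.82 in the list mean, control 4 at 1.10, and the A54 difference was 0.35. Without LKO 3 the median was 0.98 and the list did not pass, nor did it without LKO 5 (camera adjusted p = 0.141 and 0.0578). Genes of fetal and injured hepatocytes rose with a median of 0.87 (camera adjusted p = 0.00188; adjusted p = 0.401 with an estimated correlation). Adjusted over the list alone, 3 passed as higher, among them Anxa2, and Afp passed as lower. In control 4 the value was 1.13, the A54 difference was 1.37, and without control 4 the median was 1.40. Cell cycle genes rose with a median of 0.95, 30 of 34 higher (camera adjusted p = 1.19e-07; adjusted p = 0.401 with an estimated correlation). Cdk1 stood at 1.51 and Ccnb2 at 2.04, and 0 passed adjusted over the list alone, against 22 over all genes without control 4. Without LKO 3 the median was 0.55 (camera adjusted p = 1.67e-06). The value in control 4 was 1.05 and the A54 difference was 1.01.

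**Figure D4:**
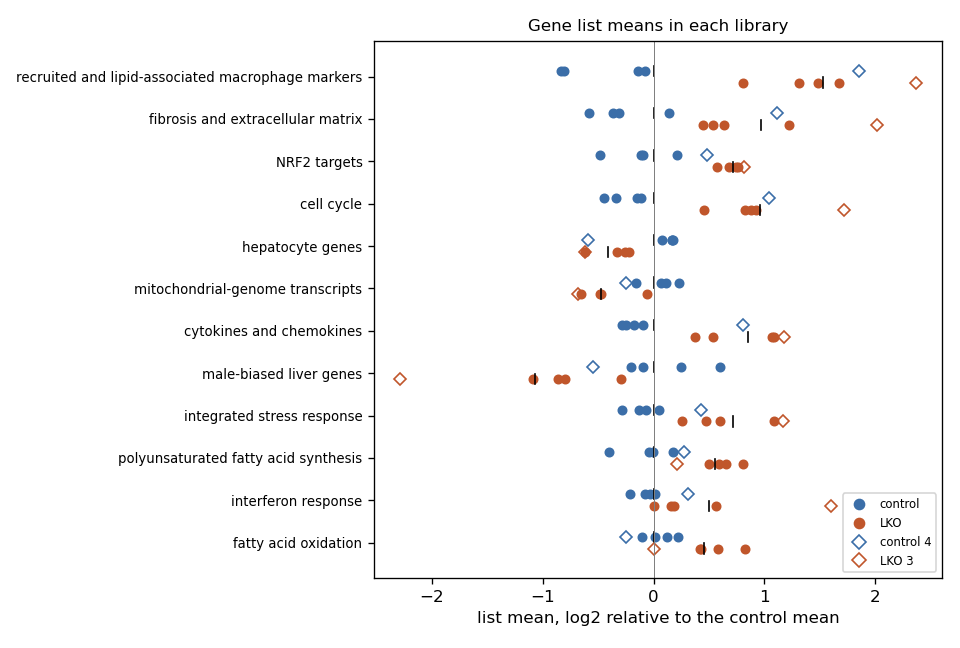
List means in each library, on the log2 scale relative to the control mean, for the 12 lists with the smallest camera p, with group means as black bars. In the macrophage list control 4 (open blue diamond) lies at 1.86, above the LKO mean of 1.53.

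Genes of polyunsaturated fatty acid synthesis and activation rose with a median of 0.58, 9 of 10 higher (camera adjusted p = 0.000241; adjusted p = 0.401 with an estimated correlation). Of the 10, 6 passed adjusted over the list alone. The elongase gene Elovl5 had 661 ± 209 CPM in control and 1305 ± 367 CPM in LKO, and the desaturase gene Fads2 720 ± 199 and 1333 ± 357 CPM. Acsl3 and Acsl5, which encode acyl-CoA synthetases, had log2 fold changes of 0.75 and 0.54. The list mean of control 4 was 0.28 in this list, and the A54 difference was 0.98. Fatty acid oxidation rose with a median of 0.21, 23 of 29 higher (camera adjusted p = 0.000527; adjusted p = 0.522 with an estimated correlation), and 9 passed adjusted over the list alone. Those with the smallest p were targets of the nuclear receptor PPARalpha, namely Cyp4a31 (1.22), Acot2 (1.35), Cyp4a14 (2.70) and Pdk4 (2.09). For control 4 it was -0.25, below the other controls, and the A54 difference was 0.41. Lipid droplet and lipid uptake genes rose with a median of 0.27 (camera adjusted p = 0.00531; adjusted p = 0.401 with an estimated correlation). The fatty acid transporter gene Cd36 had 151 ± 38.9 and 247 ± 38.6 CPM, and Cidec, of lipid droplet fusion, 40.7 ± 20.5 and 87.1 ± 22.1 CPM. Adjusted over the list alone, 6 passed as higher and 1 as lower, with control 4 at -0.02 and an A54 difference of 0.50. Cholesterol synthesis rose with a median of 0.22 (camera adjusted p = 0.0359; adjusted p = 0.641 with an estimated correlation), where Pmvk alone passed adjusted over the list, control 4 stood at 0.30 and the A54 difference was 0.60. This list did not pass without control 1, control 5, LKO 1, LKO 2 or LKO 4 (camera adjusted p = 0.127, 0.172, 0.125, 0.163 and 0.096), with medians of 0.15, 0.14, 0.18, 0.15 and 0.20.

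The other lipid lists did not pass the set test. Phospholipid synthesis and remodelling, which holds the relatives of Lpcat3, had a median of -0.01 and a mean of 0.14 (camera adjusted p = 0.8). Gpat3 (0.70) and Lpin2 (0.55), both of glycerolipid synthesis, passed adjusted over that list alone. Fatty acid synthesis had a median of 0.13 (camera adjusted p = 0.357), with Acacb at 1.19 and Srebf1 at -0.66, but passed without control 2 (median 0.41, camera adjusted p = 0.00806). Lipoprotein secretion had a median of -0.06 and a mean of 0.09 (camera adjusted p = 0.876), and Pltp (0.88), the phospholipid transfer protein gene, passed adjusted over the list alone. Its mean in control 4 was 0.02, 0.03 and -0.05 in these lists, and the A54 differences were 0.12, 0.43 and 0.23. With 1 library left out the medians ran from -0.05 (control 4) to 0.05 (LKO 3) for phospholipid synthesis, from 0.07 (control 3) to 0.41 (control 2) for fatty acid synthesis and from -0.15 (LKO 4) to 0.04 (LKO 3) for lipoprotein secretion. With 1 surrogate variable, lipoprotein secretion passed as higher (median 0.19, camera adjusted p = 0.00765).

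Transcripts of the mitochondrial genome fell as a list, with a median of -0.45 and all 13 lower in LKO (camera adjusted p = 8.65e-07; adjusted p = 0.401 with an estimated correlation). Of the 13, 5 passed adjusted over the list alone. ND4, a subunit of respiratory complex I, had 5749 ± 875 CPM in control and 3377 ± 971 CPM in LKO, and ND6 had 919 ± 106 and 593 ± 141 CPM. The mean of control 4 was -0.25 and the A54 difference was -0.38. With libraries scaled to total counts, an alternative added after the data were seen, the median was -0.22, and that of all genes was 0.235. Mitochondrial genes took 13.6 ± 0.934% of counts in control and 11.7 ± 0.81% in LKO (SD, n = 5; exact two-sided permutation p = 0.0238, adjusted p = 0.0741 over 7 library measures). Nuclear-encoded respiratory chain genes fell by a median of 0.08, 61 of 72 lower (camera adjusted p = 0.0174; adjusted p = 0.802 with an estimated correlation). None of the 72 passed adjusted over the list alone, control 4 stood at -0.36 and the A54 difference was -0.11. The list did not pass without control 1, control 2, control 5, LKO 3 or LKO 5 (camera adjusted p = 0.137, 0.0846, 0.0645, 0.988 and 0.0611). Its median was -0.04 without control 1, -0.01 without LKO 3, -0.15 without control 4 and -0.13 without LKO 4. With 1 surrogate variable, an alternative added after the data were seen, the median was 0.14 and the list passed as higher (camera adjusted p = 1.1e-09). The list of mitochondrial dynamics, mitophagy and biogenesis fell with a median of -0.11 (camera adjusted p = 0.046; adjusted p = 0.546 with an estimated correlation). Mfn1, a fusion factor, stood at -0.30 and the mitophagy receptor gene Sqstm1 at 0.52, and both passed adjusted over the list alone. In control 4 the value was -0.22 and the A54 difference was -0.14. This list did not pass without control 1, control 2, control 5, LKO 3 or LKO 5 (camera adjusted p = 0.127, 0.0716, 0.0649, 0.159 and 0.0682), and its median was -0.07 without LKO 3 and -0.18 without control 4. With 1 surrogate variable the median was 0.033 and the list did not pass. Mitochondrial chaperones and proteases did not pass, with a median of 0.08 (camera adjusted p = 0.825), control 4 at -0.20 and an A54 difference of -0.04. The median was 0.04 without control 4 or LKO 4.

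Stress pathways moved in different directions. Integrated stress response genes, targets of ATF4, rose with a median of 0.65, 20 of 23 higher (camera adjusted p = 5.12e-05; adjusted p = 0.401 with an estimated correlation). Atf5, Pck2, Slc7a11 and Vldlr were among the 8 that passed adjusted over the list alone, with log2 fold changes of 0.79, 1.33, 1.47 and 0.67. The value in control 4 was 0.43 and the A54 difference was 0.71. NRF2 targets, of the oxidative stress response, rose with a median of 0.61, 24 of 27 higher (camera adjusted p = 2.05e-08; adjusted p = 0.401 with an estimated correlation). Passing adjusted over the list alone were 12, among them Abcc4 (1.21), Srxn1 (0.85), Nqo1 (0.82) and Cbr3 (2.11). The list mean was 0.72 ± 0.09 in LKO, control 4 stood at 0.48 and the A54 difference was 0.72. Endoplasmic reticulum stress genes fell with a median of -0.25, 21 of 24 lower (camera adjusted p = 0.000527; adjusted p = 0.479 with an estimated correlation), with 0 passing adjusted over the list alone, control 4 at -0.31 and an A54 difference of -0.20. Cell death and p53 targets rose with a median of 0.21 (camera adjusted p = 0.00709; adjusted p = 0.401 with an estimated correlation). Mlkl, the effector of necroptosis, stood at 0.83, and 3 members passed adjusted over the list alone, with control 4 at 0.41 and an A54 difference of 0.38. Without LKO 4 the median was 0.12 (camera adjusted p = 0.0144). Antioxidant enzymes did not pass, with a median of -0.00 and a mean of 0.07 (camera adjusted p = 0.825), control 4 at -0.10 and an A54 difference of 0.06. With 1 library left out the median ran from -0.04 (control 3) to 0.04 (LKO 3).

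Hepatocyte genes fell as a list, with a median of -0.39 and all 25 lower (camera adjusted p = 7.06e-07; adjusted p = 0.401 with an estimated correlation). Ambp had 1604 ± 341 and 1095 ± 103 CPM, and Serpina1c, of a family of near-identical copies and so uncertain, stood at -1.06. None passed adjusted over the list alone, against 10 over all genes without control 4, which stood at -0.59. The A54 difference was -0.47. With libraries scaled to total counts, an added alternative, the list median was -0.16 and that of all genes was 0.235. Pericentral genes fell with a median of -0.39 (camera adjusted p = 0.00123; adjusted p = 0.492 with an estimated correlation), with Cyp7a1 at -1.09, control 4 at -0.59 and an A54 difference of -0.31, and 0 passing adjusted over the list alone. Without LKO 3 the median was -0.25 and the list did not pass (camera adjusted p = 0.0523). Periportal genes did not pass, with a median of -0.35 (camera adjusted p = 0.121), control 4 at -0.52 and an A54 difference of -0.38, but passed without control 4 or LKO 4 (camera adjusted p = 0.0262 and 0.0485). Bile acid synthesis and transport fell with a median of -0.40 (camera adjusted p = 0.00123; adjusted p = 0.467 with an estimated correlation). Adjusted over the list alone, Cyp7b1 (-2.01), Cyp2c70 (-1.13) and the bile acid receptor gene Nr1h4 (-0.40) passed as lower and the exporter gene Abcc4 as higher. The list mean of control 4 was -0.50 and the A54 difference was -0.45. Without LKO 3 the median was -0.26 (camera adjusted p = 0.0159). Male-biased liver genes fell with a median of -0.97, 14 of 17 lower (camera adjusted p = 5.06e-05; adjusted p = 0.401 with an estimated correlation). Hsd3b5 had 81.1 ± 56.7 and 6.59 ± 9.82 CPM, and 6 passed adjusted over the list alone, among them Nudt7 (-1.07). LKO 3 stood at -2.29 in this list, control 4 at -0.54, and the A54 difference was -1.18.

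Acute phase genes did not pass, with a median of -0.52 (camera adjusted p = 0.0645), but passed without control 1, control 2, control 4 or LKO 4 (camera adjusted p = 0.00942, 0.019, 0.014 and 0.0212). Without control 5 the median was -0.21 (camera adjusted p = 0.442). Saa1 had 560 ± 869 and 72.7 ± 13.5 CPM (log2 -2.94, and -1.33 without control 5), while Il1rn (1.45) passed adjusted over the list alone as higher. Glucose metabolism did not pass either (median -0.18, camera adjusted p = 0.357; -0.08 without control 2, -0.10 without LKO 3 and -0.11 without LKO 5), though Igfbp1 (1.78) was among those that passed adjusted over the list alone. Red blood cell genes, a measure of blood left in the tissue, did not pass (median 0.05, mean -0.08, camera adjusted p = 0.822), and with 1 library left out the median ran from -0.10 (control 1) to 0.27 (control 5). For control 4 it was -0.46, -0.13 and -0.28 in these lists, and the A54 differences were 0.16, -0.04 and 0.51. The lists of fat tissue and exocrine pancreas had 1 tested member each and were not tested. Cfd, of fat tissue, had 56.3 ± 65.5 CPM in control and 19.2 ± 16.8 CPM in LKO (log2 -1.56, and -0.55 without control 5), and Cela1, of pancreas, 3.95 ± 1.46 and 2.54 ± 0.801 CPM.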

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

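The tests of library identity for control 4 and the splits counted with edgeR (at either threshold) and camera were chosen or read only after the results were seen; the thinning test and the DESeq2 splits were set out before they were run. A sample was picked out when its gap to the nearest of the other 4 in its group exceeded 0.71 of the group's range (Dixon's criterion). Of 420 groups of 5 values, 43 met it, where chance gives about 1 in 20, or 21. Control 4 gave 25 of them and LKO 3 gave 8. Genes of one pathway move together, so these are not independent.

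Among list means relative to the controls, control 4 stood at 1.86 for recruited macrophage markers, 0.81 for cytokines and chemokines, 1.10 for cholangiocyte markers and 1.05 for the cell cycle. It stood at -0.59 for hepatocyte genes, -0.36 for the nuclear-encoded respiratory chain and -0.20 for mitochondrial chaperones and proteases. Its first principal component score was 30.2. LKO 3 stood at -0.16 for cholesterol synthesis, where the other LKO libraries lay between 0.26 and 0.42. LKO 4 stood at 0.75 for Kupffer cell markers, where the others lay between 0.01 and 0.21.

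Single genes of control 4 apart from the other controls and higher were Chka (16.96 CPM), Cbr3 (1.77 CPM), Ucp2 (36.8 CPM), Pdgfrb (24.9 CPM), Lyz2 (92.7 CPM), Cd52 (8.45 CPM) and Il1rn (16.0 CPM). Lower in control 4 were Chic1 (2.16 CPM), Srebf1 (190.1 CPM), Ndufv3 (44.9 CPM), Ndufb4 (39.3 CPM), Opa1 (107.7 CPM), Cyp2c29 (94.4 CPM) and Arg1 (452 CPM). The same held for Serpina1a (5141 CPM), Serpina1b (5402 CPM) and Serpina1c (5354 CPM), abundant secreted products of hepatocytes. In LKO 3, Abcc4 (19.1 CPM), Cd8b1 (1.02 CPM) and Cenpe (12.6 CPM) were apart and higher, and Plekhb1 (12.1 CPM), Phb (63.0 CPM), Oma1 (11.8 CPM) and Hba-a2 (46.4 CPM) were lower. In LKO 1, ND6 (840.5 CPM) was higher, while Plin3 (38.9 CPM), Sesn1 (9.45 CPM) and C1qb (2.58 CPM) were lower. Other libraries apart were control 3 for Ppp1r3g (1.11 CPM) and C1qb (1.21 CPM), control 5 for ND4 (4252 CPM), LKO 4 for Lonp1 (165 CPM) and LKO 5 for Aldh1b1 (21.1 CPM).

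Control 4 lay with the LKO libraries in macrophage, matrix and cell cycle genes. A knockout library under a control label is argued against by Lpcat3, at 95.7 CPM in control 4, 12.3 LKO SDs above the highest LKO library. Its depth, the lowest of the 10, was examined as well. With every library thinned to that depth, its gap to the other controls in the matrix list was 1.39 on the log2 scale, and it was 1.40 before. Thinning keeps the expected CPM of a gene, so the test shows only that counting noise at this depth does not make the gap. A control mouse with more advanced disease may explain the pattern, as may an uneven tissue sample, and neither was tested.

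For the count of genes changed by genotype, 3 of 100 splits of the 10 samples, the real one included, gave at least 10 genes. That share lies under 0.05, but the limit was set after the count was seen. It was not adjusted for the other counts taken from the same splits. The share therefore does not by itself exclude a chance split of the samples, and it says little about genotype. The count ran from 2 to 2296 with 1 library left out, and the splits ignore the title code, which follows the groups except in A54. With the code as a covariate edgeR called 0 genes (760 at an unadjusted p under 0.05; DESeq2 and voom were not run with it). That fit rests on 3 samples for genotype, and the Lpcat3 log2 fold change in it was -1.99 against -1.79 as reported. Code and genotype cannot be told apart outside A54, so the lost calls neither show the code to be the cause nor exclude it. The highest of the other splits gave 3179 genes, with LKO 1 among the controls in place of control 4. That is many times the real count and points to a structure of the samples, in which control 4 lies with LKO 2 to 5. For the 3402 genes with an unadjusted p under 0.05, 5 of 100 splits gave as many and the highest other gave 5480, so a chance split cannot be excluded for that count. With DESeq2, 4 of 100 splits gave at least 1175 genes, and the highest other gave 4086, again the split that exchanged control 4 and LKO 1. For the 28 gene lists, 2 of 100 splits gave as many, and the highest other gave 29. Other splits passed a median of 17 lists, so a passing list under the preset correlation is weak evidence of an effect of genotype.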

How the results depend on the processing

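Alternatives named here as added were chosen after seeing the data: leaving out control 4 and LKO 3, scaling to total counts, 1 surrogate variable, the permutation of list means and the looser threshold. EdgeR without its legacy option, run by mistake before the fit reported here, called 8 genes (3 higher, 5 lower). Lpcat3 kept its direction under every alternative run and its call under all but the title code as a covariate (-1.99, edgeR adjusted p = 0.0565; its adjusted p ran from 9.07e-39 with DESeq2 and independent filtering to 0.0565), a fit that rests on 3 samples for genotype. The number of genes called (10; 4 higher, 6 lower) depended on tool, filter and library. It was 31 (16, 15) with no filter and 20 (9, 11) with at least 1 CPM in 5 libraries, fits that tested other numbers of genes. It was 0 (0, 0) with the title code, where DESeq2 and voom were not run, and 7 without the A54 samples, with 2 lower. It was 2460 (1530, 930) by voom with quality weights, which weighted control 4 by 0.367 and LKO 3 by 0.283. DESeq2 gave 1175 (627, 548), and 1186 (634, 552) with independent filtering. Added alternatives gave 12 (9, 3) with total counts, 2363 (1495, 868) without control 4 and LKO 3, 41 (22, 19) with 1 surrogate variable, and 296 (150, 146) at an adjusted p under 0.1. At an adjusted p under 0.01 it was 2 (0, 2). Leaving out 1 library gave 2 to 2296 genes, 0 to 1568 higher and 2 to 728 lower, the highest without control 4. All 10 genes kept their call by DESeq2, by voom and without control 4 or LKO 1. With the replicate block and without control 1, 3 or 5, LKO 4 or LKO 5, Lpcat3 and Dkk4 alone did. It was 5 of 10 without control 2, LKO 2 or LKO 3, 4 without the A54 samples, 6 with total counts and 0 with the title code (760 at an unadjusted p under 0.05). On simulated counts DESeq2 made 49 false calls where edgeR made 8, so a larger DESeq2 count need not mean more true changes. Why tools differ on the real libraries was not tested.

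Replicate numbers did not pair the samples: correlations of same-numbered deviations were 0.42, 0.21, -0.23, -0.40 and -0.02, and not every sample correlated best with its own number. With a replicate block, 2 genes were called (0 higher, 2 lower) and 28 lists passed.

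Of 37 lists, 28 passed, and 20 to 29 did under other scalings, filters, samples or covariates. With an estimated correlation 0 passed, by the directional test of fry 0, and by permutation of list means 0. Without control 4, 0 passed with an estimated correlation (lowest adjusted p = 0.336) and 14 by fry. The T and NK list reversed to a median of -0.27 with at least 1 CPM in 5 libraries, which tests fewer members. With total counts 22 passed. The median of all genes was then 0.235 and that of the nuclear-encoded respiratory chain 0.16, a sign change that the common shift of all genes gives by itself. With 1 surrogate variable, camera gave 5 lists the other direction. Lipoprotein secretion (median 0.19, adjusted p = 0.00765) and the nuclear-encoded respiratory chain (0.14, adjusted p = 1.1e-09) passed as higher. Mitochondrial dynamics (0.033) did not pass, nor did cholangiocyte markers (0.0062) and pericentral genes (-0.0027), whose medians shrank to near 0 and kept their sign. The cause was not tested. Among results for single named genes, 3631 were the same, 585 gained and 89 lost the call, 21 moved and 0 reversed. At 10 libraries, edgeR recovered 70.4% of simulated 2-fold changes, with genes drawn independently and no library set apart as control 4 was. In the real libraries much larger fold changes were not called either. Examples are Hsd3b5 (log2 -3.64, edgeR adjusted p = 0.112) and Cyp4a14 (log2 2.70, edgeR adjusted p = 0.0921).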

Other observations

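The tests of hepatocyte share and of scaling in this part were chosen after the results they bear on were seen. Both patterns were found and tested on the same libraries, so what follows are hypotheses.

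Recruited macrophage markers were higher in LKO (camera adjusted p = 1.47e-08; adjusted p = 0.401 with an estimated correlation). A change of scaling moves all genes of a library alike and leaves the list mean less the median of all genes as it is. That difference was -1.36 ± 1.08 in control and 0.11 ± 0.54 in LKO (SD, n = 5; exact two-sided permutation p = 0.0397). The gap between groups was 1.48, against 1.53 for the list mean. TMM had already left almost no shift in the median of all genes between groups, so these values could hardly differ. They show a rise relative to the median gene and do not decide how far scaling sets its size. With total counts the list median was 1.35, against 1.19 with TMM. The p-value lends no independent support, since the list was picked from these data. The same permutation test of the list mean also gave p = 0.0397, and 0.0864 adjusted over 37 lists. A lower share of hepatocytes alone would raise markers of every other cell type alike. The difference between macrophage and endothelial list means was 0.00 ± 1.14 in control and 1.30 ± 0.72 in LKO (SD, n = 5; exact two-sided permutation p = 0.0714), so a lower share cannot be told apart from recruitment here (control 4 stood at 1.86 in the macrophage list). An effect of the genotype on inflammation may also explain the pattern and stays open.

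Mitochondrial-genome transcripts were lower in LKO (camera adjusted p = 8.65e-07; adjusted p = 0.401 with an estimated correlation). The list mean less the median of all genes was 8.26 ± 0.21 in control and 7.74 ± 0.27 in LKO (SD, n = 5; exact two-sided permutation p = 0.0238). The gap between groups was -0.52, against -0.47 for the list mean. As for the macrophage list, these values could hardly differ after TMM. They show a fall relative to the median gene and do not decide how far scaling sets its size. With total counts the list median was -0.22, against -0.45 with TMM, and that of all genes was 0.235. Here too the list was picked from these data. The same permutation test of the list mean also gave p = 0.0238, and 0.0864 adjusted over 37 lists. Against the nuclear-encoded respiratory chain, mitochondrial transcripts were lower by a further -0.39 in LKO (exact two-sided permutation p = 0.0238, n = 5). Against hepatocyte genes the difference was -0.06 (exact two-sided permutation p = 0.643, n = 5), and every cell type expresses the nuclear-encoded list, so a lower share of hepatocytes cannot be told apart from a lower mitochondrial transcript level per hepatocyte. An effect of Lpcat3 loss on mitochondria may be present and was not tested beyond these values.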
